A study of Drosophila melanogaster with 24 samples.

How the data were processed

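The samples are ovaries of 5 to 10 day old Drosophila melanogaster females, 15 mg per extract per the labels' protocols, lysed in a polysome buffer with cycloheximide. Per the labels, libraries were depleted of rRNA, stranded and read as pairs of 50 nt. There are 24 libraries in 8 groups of 3, which are WT input, IP5A and IP5B, RpS5b-null (5Bko) input and IP5A, and 5A-NG4 (germline RpS5a RNAi) input, IP5A and IP5B. The labels do not say whether replicates are separate animals or cultures, so p-values measure the spread between these samples, which may be technical. The WT and 5A-NG4 inputs are all titled as replicate 1, so their number was taken from the sample name.

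Per the submitters' processing notes, reads were checked with FastQC, aligned with TopHat to build dm3, counted per gene with featureCounts and compared with DESeq, with no versions given. The deposited table of normalised counts holds a signal for 15530 genes in the 24 libraries, which the authors made by dividing read counts by a size factor per library. That 1 factor per library was used was checked on the values, since dividing each column by the value of a single read gave whole numbers, within 0.05, for 100% of them, and the factors ran from 0.771 to 1.51. The authors also deposited 5 tables of precipitate against input with, per the file headers, group means of the normalised count (signal), a log2 fold change, its standard error, a p-value and an adjusted p-value. How featureCounts treated strand and reads that fit several genes is not stated, so values of genes with near copies, overlapping genes and antisense genes are uncertain. Gene symbols and FlyBase identifiers are those of the files. The reference table in hand is of another build, Release 6, and was used for synonyms of list members, with no coordinates. Gene length and GC content could not be tested, since no annotation of dm3 was at hand.

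Recovered reads per library ran from 12099722 to 22483970. Of these, 97.7% fell on protein-coding genes, 1.19% on other non-coding RNA, 0.924% on rRNA, 0.109% on snRNA and 0.0441% on snoRNA genes. No library was a copy of another (chi-square per gene of 1.89 to 68.3 over pairs of replicates), and every column of the deposited files was matched to a sample or a comparison. The precision per gene is given as the SD of 3 libraries or, for differences of ratios, as the standard error of limma.

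The main test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with trend and robust settings) on log2 of the normalised value plus 1. Genes with at least 10 in at least 3 of the 24 libraries were tested, 9031 of 15530. One model held the 8 group means of all 24 libraries. It gave 11 comparisons, which were 5 of precipitate over input, RpS5b over RpS5a precipitates in WT, 2 of mutant over WT input, and 3 differences between mutant and WT in a precipitate over input ratio. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The comparisons, the test, the gene lists and the rule for naming genes were chosen before the data were examined.

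Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over 209 tests, which are 19 lists in 11 comparisons. Beside it stand camera with the correlation estimated from the data, and fry, a rotation test. The 19 lists, with tested of found members, were cytoplasmic ribosomal proteins without RpS5a and RpS5b (83 of 86), mitochondrial ribosomal proteins (73 of 74), nuclear genes of oxidative phosphorylation (51 of 52), mitochondrially encoded mRNAs (10 of 13), TCA cycle (14 of 14), glycolysis (12 of 12), translation factors (35 of 38), proteasome (29 of 39), secretory pathway (27 of 27), stress and cell death (26 of 30), antimicrobial peptides (8 of 14), small nuclear and nucleolar RNAs (123 of 319) and long non-coding RNAs (142 of 560). For cell types they were germline (39 of 40), yolk and vitelline membrane (18 of 18), chorion (12 of 13), follicle cell regulators (21 of 22), muscle (17 of 18), and fat body, hemocyte and gut (17 of 26). Of the entries, 12 were found by a synonym and 3 were not found. Counts of list members that passed are given over all genes and adjusted over the list alone.

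Named genes follow a rule. RpS5a and RpS5b are given in every group. In each comparison the 8 largest rises and the 8 largest falls could be named among genes with a symbol other than a CG or CR number, an adjusted p below 0.05, a mean of at least 100 and, for comparisons of 2 groups, no overlap between the groups' libraries. In each called list up to 3 members with the smallest adjusted p in its direction could be named. Genes that met the rule but lost their call under an alternative were mostly left out.

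Alternatives were a pseudocount of 0.5 or 10, no filter or a filter at 100, a fit of only the groups compared, the replicate number as a block, TMM or quantile scaling, sample weights, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads, each library left out in turn, and a threshold of 0.01 for the authors' tables. Added after the data were seen were a fit without the 6 libraries of WT replicate 3 and 5A-NG4 replicate 1, fry, and camera with both an estimated correlation and the block. Pairing by replicate number was checked by correlating the deviations of same-numbered libraries from their group means. In all 5 comparisons of precipitate over input each pair had r above 0.1 (0.332 to 0.644 in WT IP5A, 0.169 to 0.387 in WT IP5B, 0.186 to 0.586 in 5Bko IP5A, 0.298 to 0.581 in 5A-NG4 IP5A and 0.248 to 0.529 in 5A-NG4 IP5B), so there the numbers were taken to pair the libraries. The RpS5b over RpS5a comparison (lowest r 0.0504) and the 2 of inputs (lowest r -0.0384 and -0.116) did not pair.

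Limma was tested on simulated counts of 8300 genes, 200 changed. For WT IP5A over input it recovered 67.2% of 67 genes changed 1.5-fold, 85.1% of 67 at 2-fold and 98.5% of 66 at 4-fold. It called 6 unchanged genes. For RpS5a ratios of RpS5b-null against WT the shares were 31.3%, 73.1% and 95.5% of as many, with 5 such genes called. The list step, on 8301 genes with proteasome genes changed 1.5-fold, called 4 of 4 of their tests and 0 of 194 of unchanged lists. An estimated correlation did too but passed 0 real tests, so false calls stay unmeasured.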

Results

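Ovarian RNA was sequenced from 24 libraries of Drosophila melanogaster, in 8 groups of 3. Females were 5 to 10 days old, and their ovaries were lysed in a polysome buffer with cycloheximide, which holds ribosomes on mRNA. The series asks which mRNAs are bound to ribosomes that carry either of the 2 paralogs of ribosomal protein S5, RpS5a and RpS5b. RpS5a or RpS5b was immunoprecipitated, and the co-precipitated RNA (IP5A and IP5B) was sequenced beside input RNA of the same genotype. Wild-type ovaries (WT) gave input, IP5A and IP5B libraries. Ovaries of RpS5b-null flies (5Bko) gave input and IP5A libraries, and ovaries with RpS5a knocked down by RNAi in the germline (named 5A-NG4 in the labels) gave all 3 kinds. No precipitation with an unrelated antibody is among the samples, so RNA that sticks to the beads was not measured apart. Library depth ran from 12099722 assigned reads in WT IP5B replicate 3 to 22483970 in 5Bko input replicate 1. By group, in Mreads (mega-reads), it was 13.8 to 15.5 in WT input, 16.8 to 17.4 in WT IP5A, 12.1 to 15.9 in WT IP5B, 12.9 to 22.5 in 5Bko input, 13.2 to 14.2 in 5Bko IP5A, 12.1 to 12.3 in 5A-NG4 input, 15.9 to 17.1 in 5A-NG4 IP5A and 13.7 to 15.0 in 5A-NG4 IP5B. Values are normalised read counts, given as mean ± SD of 3 libraries (n = 3) unless another number is named. A gene is said to rise or fall when its limma adjusted p was below 0.05, and such changes are relative to the other RNA of the same libraries. Where 2 values are set against each other, the precipitate or the mutant comes first and the input or WT second. Lists of genes were tested with camera, which compares the members with all other genes under a preset correlation between genes.

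The RpS5b-null ovaries stood apart from all others in their RNA. The first principal component of the tested genes held 57.9% of the variance and the second 17.3%. All 6 RpS5b-null libraries lay between 93.9 and 107 on the first, and the other 18 between -79.8 and -0.58. Within genotypes, the 3 libraries of WT replicate 3 and the 3 of 5A-NG4 replicate 1 (the 6 libraries below) lay farthest from their group means, with root mean square deviations of 0.361 to 0.460 and 0.355 to 0.483 on the log2 scale, as did 5Bko IP5A replicate 1 at 0.363.

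**Figure D1:**
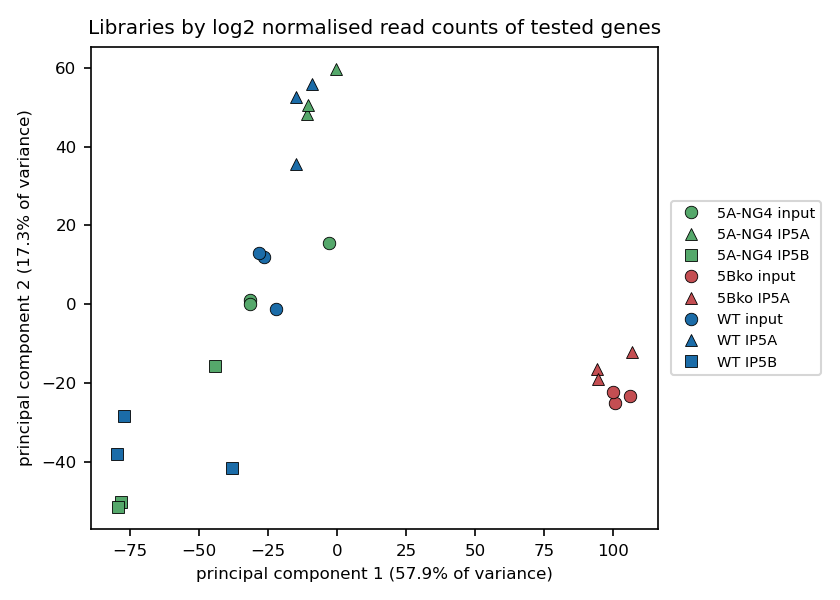
Each point is 1 of the 24 libraries, placed by its score on the first principal component (x axis, 57.9% of the variance) and the second (y axis, 17.3%) of log2 normalised read counts, with colours for the genotype and shapes for input, IP5A and IP5B. The RpS5b-null libraries lie between 93.9 and 107 on the x axis, apart from the other 18.

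The mRNA of each paralog was followed first. RpS5b (FBgn0038277) mRNA was at 14312 ± 985 in WT input and at 571 ± 14.2 in RpS5b-null input (log2 -4.64, limma adjusted p = 9.66e-16). In 5A-NG4 input it was at 14996 ± 451 (log2 0.07, not called). RpS5a (FBgn0002590) mRNA was at 10576 ± 1002 in WT input, rose to 21757 ± 1758 in RpS5b-null input (log2 1.04, limma adjusted p = 4.62e-05) and fell to 5261 ± 269 in 5A-NG4 input (by 1.00 on the log2 scale, limma adjusted p = 0.00111). The RpS5b precipitates held more RpS5b mRNA than the input, 45752 ± 6281 in WT (log2 1.67, limma adjusted p = 1.28e-07) and 46802 ± 14524 in 5A-NG4 (log2 1.59). The RpS5a precipitates held less of it, 8434 ± 868 in WT and 7027 ± 226 in 5A-NG4 (log2 -0.77 and -1.09, limma adjusted p = 0.000291 and 4.67e-06). In the RpS5b-null ovaries they held 727 ± 19.3 (log2 0.35 over input, limma adjusted p = 0.105).

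In the RpS5a precipitates both paralogs lay above the median of other cytoplasmic ribosomal proteins (log2 -1.10 in WT). RpS5a mRNA did not differ from input there by the test. It was at 11219 ± 478 in WT, 25144 ± 697 in 5Bko and 7284 ± 2665 in 5A-NG4 IP5A (log2 0.09, 0.21 and 0.39, limma adjusted p = 0.733, 0.47 and 0.0884). Its 5A-NG4 replicates had 4213, 8641 and 8997. In the RpS5b precipitates it was at 8952 ± 2022 in WT (log2 -0.26, not called) and fell to 2137 ± 118 in 5A-NG4 (log2 -1.30, limma adjusted p = 2.05e-05). The test of that difference between 5A-NG4 and WT did not pass (log2 -1.04, limma adjusted p = 0.335). Reads that fit both paralogs could be lost or shared between them, since the counting settings are not stated.

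**Figure D2:**
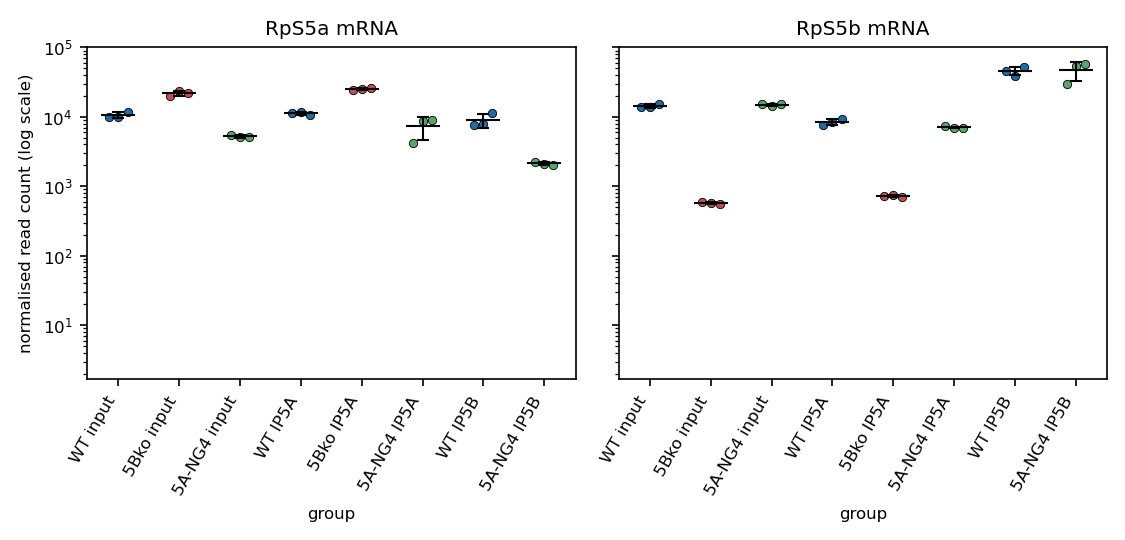
Normalised read count (y axis, log scale) of RpS5a on the left and RpS5b on the right in the 8 groups (x axis), with a point per library, a line at the mean and a bar of 1 SD (n = 3). RpS5b lies at 571 in RpS5b-null input against 14312 in WT input, and RpS5a at 5261 in 5A-NG4 input against 10576.

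The first comparison asks which mRNAs accompany RpS5a in WT ovaries. mRNAs of the protein synthesis and protein breakdown machinery were scarcer in the RpS5a precipitates than in the input. RpS24, a protein of the small ribosomal subunit, was at 3100.2 ± 206 against 9653 ± 867 (log2 -1.64, limma adjusted p = 6.21e-09). Rpn7 of the proteasome lid was at 1102 ± 65.6 against 3159 ± 72.7 (log2 -1.52) and Prosalpha7 of the proteasome core at 1594 ± 159 against 4464 ± 141. The mRNA of the Notch receptor gene N was at 13400.0 ± 1886 against 6693 ± 943 (log2 1.00, limma adjusted p = 4.13e-05). The largest rises among named genes included the calcium channel gene cac (481 ± 80.2 against 164 ± 33.3), the dynein heavy chain Dhc36C (1877 ± 166 against 649.7 ± 79.3) and the metallothionein MtnA (1002 ± 161 against 326 ± 47.7), at log2 1.56, 1.53 and 1.61.

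In WT RpS5a precipitates, 83 of 83 cytoplasmic ribosomal protein genes, 28 of 29 proteasome genes and 24 of 35 translation factor genes fell, and 0, 0 and 3 rose; adjusted over the list alone 83, 29 and 24 fell and 0, 0 and 3 rose. Their median log2 changes were -1.10, -1.24 and -0.47. Camera gave adjusted p = 2.61e-31, 7.37e-19 and 1.43e-05, and adjusted p = 0.697 to 0.706 with an estimated correlation. In WT RpS5a precipitates, 68 of 73 mitochondrial ribosomal protein genes, 46 of 51 nuclear genes of oxidative phosphorylation, 11 of 14 TCA cycle genes and 9 of 12 glycolysis genes fell, and 0, 0, 1 and 1 rose; adjusted over the list alone 69, 46, 11 and 9 fell and 0, 0, 1 and 1 rose. The medians, in this order, were log2 -0.75, -0.80, -0.41 and -0.92. By camera, adjusted p = 9.25e-18, 1.27e-14, 0.000874 and 0.000174, with adjusted p = 0.697 to 0.706 with an estimated correlation. Examples were mRpL21 at 375 ± 39.0 against 777 ± 36.7, the ATP synthase subunit ATPsyn-beta at 9786 ± 233 against 24049.9 ± 1228, malate dehydrogenase Mdh2 at 1945 ± 111 against 4021 ± 35.8 and the glycolytic enzyme Gapdh2 at 8323 ± 509 against 23866 ± 69.6. In WT RpS5a precipitates, 15 of 27 secretory pathway genes and 105 of 123 small nuclear and nucleolar RNAs fell, and 1 and 1 rose; adjusted over the list alone 15 and 107 fell and 1 and 1 rose. As log2 changes the medians were -0.41 and -2.31. In the camera test adjusted p = 0.00846 and 3.93e-22, and adjusted p = 0.673 to 0.775 with an estimated correlation. In WT RpS5a precipitates, 13 of 21 follicle cell regulators rose, and 0 fell (16 and 0 adjusted over the list alone). The median change was log2 0.91. Adjusted p = 0.0002 in camera, and adjusted p = 0.697 with an estimated correlation. Lists that did not pass had medians of -2.12 for mitochondrially encoded mRNAs (0 rose and 2 fell of 10), 0.08 for germline genes (13 rose and 11 fell of 39), 0.22 for yolk and vitelline membrane genes (3 rose and 0 fell of 18), 0.19 for muscle genes (2 rose and 0 fell of 17) and 0.23 for long non-coding RNAs (16 rose and 19 fell of 142). The mitochondrially encoded mRNAs passed when the replicate number was a block in the model (camera adjusted p = 0.00076, and adjusted p = 0.636 with the block and an estimated correlation). They also passed without WT input replicate 3 (-2.49) or WT IP5A replicate 2 (-2.33), with no filter (-1.90), with sample weights (-1.99) and in a fit of the 2 groups alone. The weights converged slowly, so calls with them are uncertain throughout.

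In this comparison 4461 of 9031 genes passed in limma, 2195 higher and 2266 lower in the precipitates, of which 259 and 450 differed by at least 2-fold. With TMM scaling the split was 1601 higher and 2632 lower.

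The RpS5b precipitates of WT ovaries held a different set. Among the largest rises of named genes were MED18, a Mediator subunit, at 1306 ± 124 against 387 ± 30.3 (log2 1.75, limma adjusted p = 1.72e-08), Roc2, a RING protein of cullin ubiquitin ligases, at 1782 ± 264 against 538 ± 16.7, e(y)2, which acts in mRNA export and SAGA, at 1002 ± 140.5 against 324 ± 18.4, and the ubiquitin-like Nedd8 at 3672 ± 514 against 1232 ± 38.7. Of muscle genes, wupA (troponin I) was at 46.8 ± 34.8 against 237 ± 15.7 and Mlc1 (a myosin light chain) at 28.3 ± 17.0 against 121 ± 8.94. Of mRNAs made inside mitochondria, mt:Cyt-b was at 43.6 ± 31.6 against 772 ± 280.2 and mt:CoIII at 141 ± 68.7 against 2082 ± 792 (log2 -3.90).

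In WT RpS5b precipitates, 66 of 73 mitochondrial ribosomal protein genes, 48 of 51 nuclear genes of oxidative phosphorylation and 28 of 29 proteasome genes rose, and 1, 0 and 0 fell; adjusted over the list alone 68, 48 and 28 rose and 1, 0 and 0 fell. Median changes were log2 0.68, 0.90 and 0.60 in list order. The camera test had adjusted p = 1.3e-18, 1.79e-17 and 2.68e-10, and adjusted p = 0.697 with an estimated correlation. In WT RpS5b precipitates, 8 of 12 glycolysis genes and 11 of 83 cytoplasmic ribosomal protein genes rose, and 1 and 1 fell; adjusted over the list alone 10 and 2 rose and 1 and 0 fell. These lists had medians of log2 0.33 and 0.14. With camera, adjusted p = 0.00285 and 0.0276, and adjusted p = 0.734 to 0.918 with an estimated correlation. The call of the cytoplasmic ribosomal proteins ended with quantile scaling (median log2 0.04) and a filter at 100 (0.14), and without the 6 libraries (0.05), WT IP5B replicate 3 (-0.01), WT input replicate 1 (0.10) or WT input replicate 2 (0.10).

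In WT RpS5b precipitates, 14 of 17 muscle genes, 9 of 10 mitochondrially encoded mRNAs and 120 of 123 small nuclear and nucleolar RNAs fell, and 0, 0 and 0 rose; adjusted over the list alone 15, 10 and 122 fell and 0, 0 and 0 rose. For the lists, median log2 changes were -1.56, -3.87 and -2.66. Camera gave adjusted p = 1.17e-05, 0.00422 and 2.63e-33, and adjusted p = 0.231 to 0.775 with an estimated correlation. In WT RpS5b precipitates, 11 of 18 yolk and vitelline membrane genes and 11 of 21 follicle cell regulators fell, and 0 and 1 rose; adjusted over the list alone 12 and 12 fell and 0 and 1 rose. Their median log2 changes were -0.96 and -0.72. By camera, adjusted p = 0.00285 and 0.0279, with adjusted p = 0.779 with an estimated correlation. The follicle cell call ended with quantile scaling (median log2 -0.15), without WT IP5B replicate 2 (-0.46) and without WT input replicate 2 (-0.73). Lists that did not pass had medians of 0.11 for TCA cycle genes (4 rose and 1 fell of 14), 0.00 for germline genes (7 rose and 14 fell of 39), -0.78 for chorion genes (0 rose and 5 fell of 12) and -1.65 for fat body, hemocyte and gut markers (0 rose and 5 fell of 17). With the replicate block, the chorion and the fat body, hemocyte and gut lists passed (camera adjusted p = 0.00702 and 0.00467, and adjusted p = 0.65 and 0.636 with the block and an estimated correlation). Without WT input replicate 3 both passed (-0.90 and -1.57), as did chorion without WT IP5B replicate 1 (-0.83), and both with no filter, TMM scaling, sample weights and the 2 groups alone. By gene, 4377 of 9031 passed in limma, 2083 higher and 2294 lower, with 240 and 798 at 2-fold or more, and with TMM scaling the split was 2525 and 1755.

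Set directly against each other, with no input between them, the RpS5b and RpS5a precipitates of WT ovaries differed in most genes. Ssb-c31a, a single-stranded DNA-binding coactivator, was at 3792 ± 617 with RpS5b and 394 ± 1.71 with RpS5a (log2 3.25, limma adjusted p = 7.98e-12). The replication factor C subunit RfC4 was at 3403 ± 439 against 588 ± 83.9 and Nedd8 at 3672 ± 514 against 618 ± 37.8. In the other direction, the ionotropic receptor gene Ir7c was at 291 ± 113 with RpS5b and 2325 ± 324 with RpS5a, and cac at 87.3 ± 18.5 against 481 ± 80.2. The somatic gonad transcription factor tj was at 509.9 ± 134 against 1567 ± 358. The protease gene ndl, of the yolk and vitelline membrane list, was at 687 ± 91.4 against 2289 ± 304.

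Counted as RpS5b over RpS5a precipitate, 83 of 83 cytoplasmic ribosomal protein genes, 29 of 29 proteasome genes, 72 of 73 mitochondrial ribosomal protein genes and 49 of 51 nuclear genes of oxidative phosphorylation rose, and 0, 0, 0 and 0 fell (the same adjusted over the list alone). The medians, in this order, were log2 1.22, 1.91, 1.40 and 1.73. In the camera test adjusted p = 2.14e-22, 1.46e-16, 1.81e-22 and 3.13e-19, and adjusted p = 0.697 with an estimated correlation. RpL32 was at 8662 ± 1725 against 2647 ± 318, Prosalpha5 at 6193 ± 717 against 1390.1 ± 72.9 and mRpL32 at 1099 ± 152 against 271 ± 32.6. With RpS5b over RpS5a, 10 of 12 glycolysis genes, 12 of 14 TCA cycle genes, 25 of 35 translation factor genes and 19 of 27 secretory pathway genes rose, and 2, 2, 3 and 2 fell (the same adjusted over the list alone). As log2 changes the medians were 1.42, 0.32, 0.51 and 0.53. Adjusted p = 0.000228, 0.00455, 0.00014 and 0.0048 in camera, and adjusted p = 0.697 to 0.775 with an estimated correlation. With RpS5b over RpS5a, 19 of 21 follicle cell regulators, 16 of 17 muscle genes and 15 of 18 yolk and vitelline membrane genes fell, and 0, 0 and 0 rose; adjusted over the list alone 20, 16 and 15 fell and 0, 0 and 0 rose. The list medians were log2 -1.52, -1.82 and -1.05. The camera test had adjusted p = 0.000249, 0.00128 and 0.0124, and adjusted p = 0.697 to 0.815 with an estimated correlation. Germline genes had a median of -0.20 and did not pass (10 rose and 19 fell of 39), nor did fat body, hemocyte and gut markers (median -2.03, 9 of 17 lower), though these passed with TMM scaling (-1.86) and sample weights (-2.79).

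In all 6643 of 9031 genes passed in limma, 2821 higher and 3822 lower with RpS5b, 1164 and 1626 of them by at least 2-fold, while with TMM scaling more were higher (3276) than lower (3059). The median of all genes was -0.24 on the log2 scale here, -0.07 with TMM and -0.10 with quantile scaling, so smaller shifts are read against that offset.

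The next comparison asks which mRNAs accompany RpS5a when RpS5b is absent. In RpS5b-null ovaries RpS20 mRNA was at 8515 ± 601 in the RpS5a precipitates and 15959 ± 1761 in the input (log2 -0.90, limma adjusted p = 1.77e-05), and RpS2 fell by 0.81 on the log2 scale. Arc1, which encodes a capsid-forming protein, fell from 10123 ± 316 to 1379 ± 9.57 (log2 -2.87), the largest fall of a protein-coding gene named here. The actin-binding Unc-115a rose to 8420.0 ± 2517 from 2495 ± 137 (log2 1.72, limma adjusted p = 0.00262), the adhesion receptor gene Cirl to 10496 ± 3627 from 4086 ± 152, and Dhc36C and cac, which also rose in WT, by log2 1.35 and 1.32.

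In RpS5b-null RpS5a precipitates, 35 of 83 cytoplasmic ribosomal protein genes, 19 of 29 proteasome genes and 13 of 35 translation factor genes fell, and 0, 0 and 2 rose; adjusted over the list alone 45, 21 and 18 fell and 0, 0 and 3 rose. Median changes were log2 -0.33, -0.36 and -0.25 in list order. With camera, adjusted p = 1.95e-13, 2.87e-09 and 0.000265, and adjusted p = 0.706 to 0.749 with an estimated correlation. In RpS5b-null RpS5a precipitates, 9 of 14 TCA cycle genes, 6 of 12 glycolysis genes and 5 of 27 secretory pathway genes fell, and 0, 0 and 0 rose; adjusted over the list alone 12, 7 and 5 fell and 0, 0 and 0 rose. These lists had medians of log2 -0.26, -0.32 and -0.25. Camera gave adjusted p = 1.17e-05, 0.000101 and 0.00562, and adjusted p = 0.673 to 0.775 with an estimated correlation. In RpS5b-null RpS5a precipitates, 95 of 123 small nuclear and nucleolar RNAs fell, and 2 rose (102 and 2 adjusted over the list alone). On the log2 scale the median was -2.20. By camera, adjusted p = 1.57e-35, with adjusted p = 0.231 with an estimated correlation. The call of the translation factors ended with quantile scaling (median log2 -0.10).

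In RpS5b-null RpS5a precipitates, 11 of 73 mitochondrial ribosomal protein genes, 9 of 51 nuclear genes of oxidative phosphorylation, 2 of 18 yolk and vitelline membrane genes, 2 of 12 chorion genes and 4 of 17 muscle genes fell, and 0, 0, 0, 0 and 0 rose; adjusted over the list alone 7, 9, 1, 2 and 4 fell and 0, 0, 0, 0 and 0 rose. Their median log2 changes were -0.12, -0.11, -0.47, -0.80 and -0.48. In the camera test adjusted p = 0.0244, 0.0472, 0.0116, 0.00291 and 0.0263, and adjusted p = 0.749 to 0.918 with an estimated correlation. In RpS5b-null RpS5a precipitates, 25 of 142 long non-coding RNAs rose, and 13 fell (28 and 13 adjusted over the list alone). The median change was log2 0.40. Adjusted p = 0.0177 in camera, and adjusted p = 0.775 with an estimated correlation. Of these 6 calls, 5 ended without 5Bko IP5A replicate 1, with medians of -0.03 (mitochondrial ribosomal proteins), 0.00 (oxidative phosphorylation), -0.21 (yolk), -0.04 (chorion) and 0.19 (long non-coding RNAs). Sample weights ended the same 5 (-0.07, -0.05, -0.35, -0.34 and 0.27), and no filter (0.11) or a filter at 100 (0.25) the long non-coding RNA call. The oxidative phosphorylation call also ended with a pseudocount of 10 (-0.11), a filter at 100 (-0.11), quantile scaling (-0.09) and the 2 groups alone (-0.11), and without the 6 libraries (camera adjusted p = 0.0503) or 5Bko input replicate 2 (-0.09), and with the replicate block (camera adjusted p = 0.0589). The muscle call ended without 5Bko IP5A replicate 2 (-0.44) and with the block (camera adjusted p = 0.0588), where the mitochondrially encoded mRNAs passed (camera adjusted p = 0.0144, and adjusted p = 0.662 with the block and an estimated correlation), as they did without 5Bko IP5A replicate 1 (median -2.06). Follicle cell regulators (median 0.16) and germline genes (median 0.05) did not pass. By gene, 2217 of 9031 passed in limma, 1173 higher and 1044 lower, 90 and 118 of them by at least 2-fold, with TMM scaling 946 and 1100, and 3861 passed without the 6 libraries.

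With RpS5a knocked down in the germline, the RpS5a precipitates were poor in ribosomal and proteasomal mRNAs, as in WT. RpS24 was at 3033 ± 486 in the precipitates and 11517 ± 247 in the input (log2 -1.94, limma adjusted p = 5.29e-10), the proteasome core gene Pros35 at 1159.6 ± 159 against 4239 ± 118 and CG10219 at 259 ± 28.6 against 893 ± 29.2. N was at 12205 ± 1084 against 6398 ± 226 and the zinc finger gene peb at 1234 ± 89.6 against 648 ± 181. Among the largest rises were sty, an inhibitor of receptor tyrosine kinase signalling, at 602 ± 81.9 against 235 ± 19.9 and brk, a repressor of BMP targets, at 288 ± 98.3 against 103 ± 12.3.

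In 5A-NG4 RpS5a precipitates, 82 of 83 cytoplasmic ribosomal protein genes, 29 of 29 proteasome genes and 24 of 35 translation factor genes fell, and 0, 0 and 3 rose (the same adjusted over the list alone). As log2 changes the medians were -1.37, -1.46 and -0.43. The camera test had adjusted p = 6.06e-34, 1.83e-18 and 6.2e-05, and adjusted p = 0.697 to 0.727 with an estimated correlation. In 5A-NG4 RpS5a precipitates, 73 of 73 mitochondrial ribosomal protein genes, 51 of 51 nuclear genes of oxidative phosphorylation, 12 of 14 TCA cycle genes and 9 of 12 glycolysis genes fell, and 0, 0, 0 and 0 rose (the same adjusted over the list alone). The list medians were log2 -1.02, -1.12, -0.57 and -1.21. With camera, adjusted p = 1.81e-22, 9.17e-18, 0.000168 and 2.96e-05, and adjusted p = 0.697 with an estimated correlation. In 5A-NG4 RpS5a precipitates, 108 of 123 small nuclear and nucleolar RNAs and 16 of 27 secretory pathway genes fell, and 1 and 1 rose; adjusted over the list alone 109 and 16 fell and 1 and 1 rose. Median changes were log2 -2.57 and -0.40 in list order. Camera gave adjusted p = 1.37e-19 and 0.0116, and adjusted p = 0.673 to 0.779 with an estimated correlation. In 5A-NG4 RpS5a precipitates, 13 of 21 follicle cell regulators rose, and 0 fell (14 and 0 adjusted over the list alone). The median change was log2 0.80. By camera, adjusted p = 0.000315, with adjusted p = 0.697 with an estimated correlation. The secretory call ended without 5A-NG4 input replicate 1 (median -0.24), and the mitochondrially encoded mRNAs passed with the replicate block (median -1.92, camera adjusted p = 0.00794, and adjusted p = 0.65 with the block and an estimated correlation) and without 5A-NG4 IP5A replicate 1 (-3.17). Germline genes and long non-coding RNAs did not pass, with medians of 0.07 and 0.06 but means of -0.04 and -0.06. By gene, 4828 of 9031 passed in limma, 2274 higher and 2554 lower, 238 and 739 of them by at least 2-fold.

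The RpS5b precipitates of 5A-NG4 ovaries were rich in phol, a DNA-binding protein of the Polycomb system. phol was at 10024 ± 1149 against 2896 ± 87.2 (log2 1.78, limma adjusted p = 1.83e-12) and Tom7 of the mitochondrial import pore at 2754 ± 849.7 against 952 ± 78.6. The eggshell genes dec-1 and Cp15 were at 7781 ± 4924 against 21974 ± 8543 and 8684 ± 2074 against 16256 ± 2425.

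In 5A-NG4 RpS5b precipitates, 65 of 73 mitochondrial ribosomal protein genes, 49 of 51 nuclear genes of oxidative phosphorylation, 26 of 29 proteasome genes and 9 of 12 glycolysis genes rose, and 1, 0, 0 and 1 fell; adjusted over the list alone 66, 49, 26 and 10 rose and 1, 0, 0 and 1 fell. For the lists, median log2 changes were 0.61, 0.79, 0.47 and 0.35. In the camera test adjusted p = 1.45e-15, 5.52e-16, 8.14e-08 and 0.00916, and adjusted p = 0.697 to 0.775 with an estimated correlation. In 5A-NG4 RpS5b precipitates, 15 of 18 yolk and vitelline membrane genes, 5 of 12 chorion genes and 14 of 21 follicle cell regulators fell, and 0, 0 and 1 rose; adjusted over the list alone 16, 5 and 14 fell and 0, 0 and 1 rose. Their median log2 changes were -1.08, -1.09 and -0.78. Adjusted p = 8.86e-05, 0.0116 and 0.00205 in camera, and adjusted p = 0.725 to 0.775 with an estimated correlation. In 5A-NG4 RpS5b precipitates, 15 of 17 muscle genes, 12 of 17 fat body, hemocyte and gut markers and 6 of 8 antimicrobial peptide genes fell, and 0, 0 and 0 rose; adjusted over the list alone 15, 15 and 6 fell and 0, 0 and 0 rose. The medians, in this order, were log2 -2.18, -2.15 and -1.75. The camera test had adjusted p = 1.35e-07, 0.00285 and 0.0391, and adjusted p = 0.697 with an estimated correlation. In 5A-NG4 RpS5b precipitates, 10 of 10 mitochondrially encoded mRNAs and 117 of 123 small nuclear and nucleolar RNAs fell, and 0 and 0 rose; adjusted over the list alone 10 and 118 fell and 0 and 0 rose. As log2 changes the medians were -3.63 and -2.76. With camera, adjusted p = 0.00464 and 1.51e-35, and adjusted p = 0.231 to 0.775 with an estimated correlation. The 83 cytoplasmic ribosomal proteins had a median of 0.01 and did not pass (4 rose and 5 fell, 1 and 3 adjusted over the list alone), and germline genes had a median of 0.03 with a mean of -0.02. The ribosomal proteins passed higher without 5A-NG4 IP5B replicate 1 (0.18, camera adjusted p = 0.0202), with sample weights (0.18) and without the 6 libraries (0.18).

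The antimicrobial peptide call ended without 5A-NG4 IP5B replicate 1 (median -1.77, camera adjusted p = 0.1), without 5A-NG4 input replicate 2 (-1.76), with a pseudocount of 10 (-0.51), with quantile scaling (-0.74), with sample weights (-1.92) and without the 6 libraries (-1.90), where chorion ended too (-1.18). Quantile scaling also ended the follicle cell (-0.35) and fat body, hemocyte and gut (-1.15) calls. By gene, 4585 of 9031 passed in limma, 2246 higher and 2339 lower, 198 and 950 of them by at least 2-fold, and with TMM scaling the split was 2867 and 1702.

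**Figure D3:**
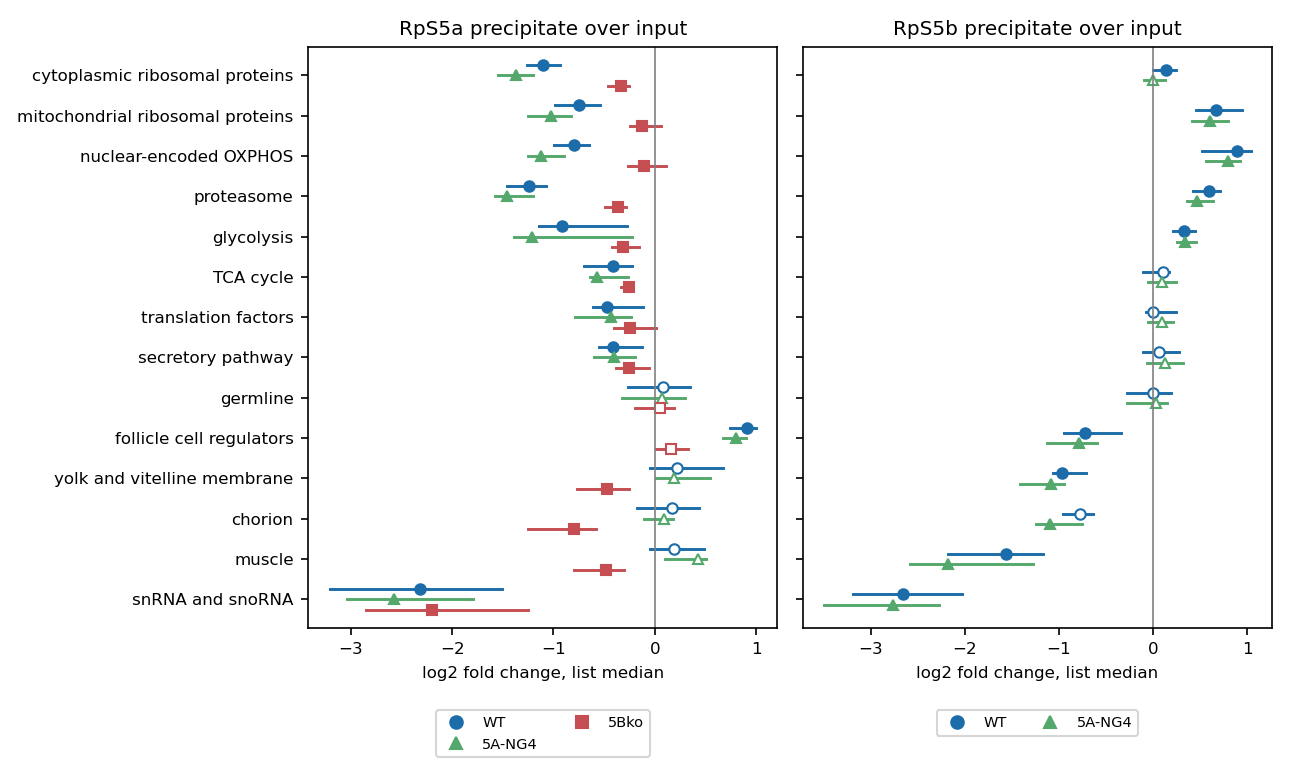
Log2 change of precipitate over input (x axis) for 14 gene lists (y axis), RpS5a precipitates on the left and RpS5b precipitates on the right, with circles for WT, triangles for 5A-NG4 and squares for RpS5b-null. Markers are list medians, lines the quartiles, and filled markers passed camera with the preset correlation, such as cytoplasmic ribosomal proteins at -1.10 in WT and -0.33 in RpS5b-null RpS5a precipitates.

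The inputs compare steady-state RNA between genotypes or strains, and the loss of RpS5b went with a wide change. Of germline genes, nos, a translational repressor of germ cells, was at 2839.6 ± 215 against 13939.6 ± 276 (log2 -2.30, limma adjusted p = 4.2e-16), BicC at 6816 ± 373 against 22966 ± 1508 and pgc, which silences transcription in germ cell precursors, at 1441 ± 85.4 against 4277 ± 131. The chorion genes Cp15 and Cp16, made by late follicle cells, were at 2974 ± 624 against 12623 ± 316 and 1175 ± 231 against 4773 ± 677. Of stress and cell death genes, the pro-apoptotic W (hid) was at 1008 ± 58.0 against 121 ± 18.3, GstD2, a glutathione transferase, at 1234 ± 119.8 against 67.3 ± 9.07, and Xrp1, a transcription factor that acts when ribosomal proteins are short, at 2007 ± 112 against 420.4 ± 35.1 (log2 2.25, limma adjusted p = 6.98e-12). The largest rises among named genes included the gluconeogenic Pepck at 11298 ± 1758 against 82.2 ± 40.0 and the receptor tyrosine kinase gene sev at 4384 ± 202 against 81.2 ± 14.5, and the largest falls bora (83.7 ± 21.9 against 878 ± 69.2) and w (18.5 ± 2.30 against 1016 ± 60.2).

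In RpS5b-null inputs, 23 of 39 germline genes, 10 of 12 chorion genes and 8 of 12 glycolysis genes fell, and 6, 0 and 2 rose; adjusted over the list alone 23, 11 and 8 fell and 6, 0 and 2 rose. The list medians were log2 -0.50, -2.02 and -0.70. Camera gave adjusted p = 0.000799, 0.0048 and 0.0477, and adjusted p = 0.697 to 0.815 with an estimated correlation. In RpS5b-null inputs, 17 of 21 follicle cell regulators, 17 of 17 muscle genes and 18 of 26 stress and cell death genes rose, and 2, 0 and 7 fell (the same adjusted over the list alone). Median changes were log2 2.48, 2.20 and 1.47 in list order. By camera, adjusted p = 0.000237, 0.000234 and 0.0246, with adjusted p = 0.697 to 0.734 with an estimated correlation. peb, a zinc finger gene of follicle cells, was at 3498 ± 18.7 against 546 ± 99.3 and Zasp52 of the muscle Z-disc at 1119.9 ± 125 against 296 ± 30.0. Fat body, hemocyte and gut markers had a median of 1.39 and did not pass (8 rose and 1 fell of 17), nor did yolk and vitelline membrane genes (median -0.26, 7 and 8 of 18).

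In RpS5b-null inputs, 82 of 83 cytoplasmic ribosomal protein genes, 51 of 73 mitochondrial ribosomal protein genes and 30 of 35 translation factor genes rose, and 1, 0 and 2 fell; adjusted over the list alone 82, 49 and 31 rose and 1, 0 and 2 fell. These lists had medians of log2 0.74, 0.39 and 0.66. In the camera test adjusted p = 2.37e-10, 0.00102 and 1.36e-05, and adjusted p = 0.706 to 0.87 with an estimated correlation. RpL23A was at 18575 ± 1683 against 4372 ± 346. In RpS5b-null inputs, 38 of 51 nuclear genes of oxidative phosphorylation, 20 of 27 secretory pathway genes and 79 of 123 small nuclear and nucleolar RNAs rose, and 0, 1 and 0 fell; adjusted over the list alone 38, 20 and 75 rose and 0, 1 and 0 fell. For the lists, median log2 changes were 0.50, 0.41 and 1.08. Adjusted p = 0.000494, 0.0246 and 0.00102 in camera, and adjusted p = 0.779 to 0.851 with an estimated correlation. The secretory call ended with TMM scaling (median 0.11), and that of the small nuclear and nucleolar RNAs turned to a median of -0.15 with quantile scaling (camera adjusted p = 0.963). The glycolysis call ended without 5Bko input replicate 1 (-0.65), WT input replicate 2 (-0.71) or WT input replicate 3 (-0.66), with a filter at 100 (-0.71) and sample weights (-0.64), and the stress call with the 2 groups alone (camera adjusted p = 0.058) and sample weights (1.39).

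By gene, 6797 of 9031 passed in limma, 3724 higher and 3073 lower in RpS5b-null inputs, 2179 and 925 of them by at least 2-fold. TMM scaling moved the median of all genes from 0.13 to -0.17 on the log2 scale and the split to 2749 higher and 4060 lower, so list medians are read against that offset.

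Germline knock-down of RpS5a went with 791 changed genes in the input. nrv3, a subunit of the sodium pump, was at 7.09 ± 2.37 against 1165 ± 138 (log2 -7.21, limma adjusted p = 1.32e-14) and alpha-Est10, an esterase, at 241 ± 27.7 against 1616 ± 63.4. The cytochrome P450 gene Cyp6d4 was at 508 ± 16.8 against 93.7 ± 40.2. Ribosomal protein mRNAs moved little (median 0.20 over 83 genes), and germline genes had a median of -0.04 (1 rose and 4 fell of 39, not called).

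In 5A-NG4 inputs, 2 of 83 cytoplasmic ribosomal protein genes rose, and 1 fell (0 and 1 adjusted over the list alone). The list median was log2 0.20. The camera test had adjusted p = 9.69e-08, and adjusted p = 0.815 with an estimated correlation. In 5A-NG4 inputs, 0 of 27 secretory pathway genes fell, and 0 rose (the same adjusted over the list alone). On the log2 scale the median was -0.13. With camera, adjusted p = 0.0252, and adjusted p = 0.815 with an estimated correlation. The secretory call ended without 5A-NG4 input replicate 2 (-0.05), 5A-NG4 input replicate 3 (-0.06) or WT input replicate 3 (-0.14), with the 2 groups alone (-0.13) and quantile scaling (-0.13), and fry passed neither list. Yolk and vitelline membrane genes, uncalled at a median of -0.28, passed lower without 5A-NG4 input replicate 1 (-0.62), with sample weights (-0.58) and without the 6 libraries (-0.63). Median and mean differed in sign for stress and cell death (0.08 and -0.10), glycolysis (0.03 and -0.01) and chorion genes (-0.10 and 0.01), none of them called. By gene, 791 of 9031 passed in limma, 410 higher and 381 lower, 171 and 136 of them by at least 2-fold, and with TMM scaling 325 and 490. The count fell to 498 without WT input replicate 1 and to 521 without 5A-NG4 input replicate 2, and was 2179 without the 6 libraries.

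**Figure D4:**
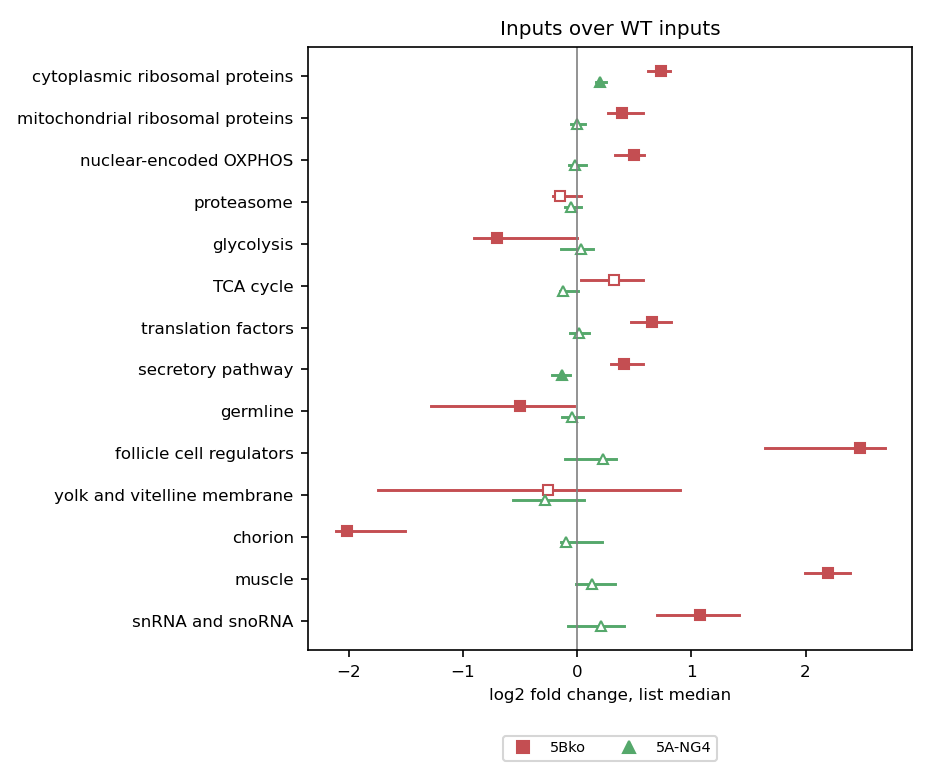
Log2 change of input over WT input (x axis) for the gene lists (y axis), with squares for RpS5b-null and triangles for 5A-NG4 ovaries, markers at list medians and lines over the quartiles. Filled markers passed camera with the preset correlation, such as muscle genes at 2.20 and chorion genes at -2.02 in RpS5b-null inputs.

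The design also asks whether the association with RpS5a changes without RpS5b, which is the difference between the precipitate over input ratios of RpS5b-null and WT ovaries. Ribosomal, proteasomal and respiratory mRNAs were less depleted in the RpS5b-null precipitates. The difference was log2 1.47 ± 0.25 SE for RpL38 and 1.34 ± 0.19 SE for Pros35 (limma adjusted p = 0.000404 and 6.81e-05). For Gapdh2 it was 1.16 ± 0.16 SE (all n = 3 libraries in each of 4 groups). Ssb-c31a had the largest among named genes (log2 2.14 ± 0.26 SE, limma adjusted p = 2.18e-05), and Grip75, of the gamma-tubulin complex, RfC4 and the small heat shock gene Hsp26 were at log2 1.55, 1.57 and 1.56. kibra, ImpL2 and the translation inhibitor Thor went the other way (log2 -1.65 ± 0.44, -1.62 ± 0.24 and -1.65 ± 0.40 SE). So did the follicle cell genes mirr and tj (log2 -2.11 ± 0.47 and -1.20 ± 0.26 SE). RpS5a differed by 0.12 and RpS5b by 1.11 (limma adjusted p = 0.783 and 0.00101). RpS5b was at 571 in RpS5b-null input, so reads possibly shared with RpS5a leave that ratio uncertain.

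Counted as RpS5b-null minus WT, 68 of 83 cytoplasmic ribosomal protein genes, 50 of 73 mitochondrial ribosomal protein genes, 36 of 51 nuclear genes of oxidative phosphorylation and 26 of 29 proteasome genes rose, and 0, 0, 0 and 0 fell; adjusted over the list alone 71, 60, 40 and 28 rose and 0, 0, 1 and 0 fell. As log2 changes the medians were 0.81, 0.68, 0.80 and 0.83. Camera gave adjusted p = 1.2e-22, 1.07e-16, 5.11e-14 and 1.36e-15, and adjusted p = 0.697 to 0.706 with an estimated correlation. By difference of ratios, 8 of 12 glycolysis genes and 8 of 35 translation factor genes rose, and 2 and 0 fell (the same adjusted over the list alone). The list medians were log2 0.52 and 0.24. By camera, adjusted p = 0.0195 and 0.017, with adjusted p = 0.775 to 0.815 with an estimated correlation. By difference of ratios, 5 of 21 follicle cell regulators, 2 of 17 muscle genes, 4 of 18 yolk and vitelline membrane genes and 2 of 12 chorion genes fell, and 0, 0, 0 and 0 rose; adjusted over the list alone 8, 2, 4 and 2 fell and 0, 0, 0 and 0 rose. Median changes were log2 -0.63, -0.62, -0.63 and -1.22 in list order. In the camera test adjusted p = 0.00023, 0.0104, 0.00285 and 0.00941, and adjusted p = 0.697 to 0.815 with an estimated correlation. Without 5Bko IP5A replicate 1 the chorion median was -0.17 and the yolk median -0.31, and neither passed, nor did chorion with sample weights (-0.41). The translation factor call ended without 5Bko IP5A replicate 3 (0.23) or 5Bko input replicate 1 (0.21), and the mitochondrially encoded mRNAs passed with the replicate block (median 1.30, camera adjusted p = 0.0417, and adjusted p = 0.731 with the block and an estimated correlation). Germline genes had a median of 0.02 with a mean of -0.01 and did not pass. By gene, 2209 of 9031 passed in limma, 1360 higher and 849 lower, 201 and 81 of them by at least 2-fold, and with TMM scaling 1660 and 514. Without the 6 libraries, 3676 genes passed.

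The association with RpS5a was compared in the same way between 5A-NG4 and WT ovaries. No gene passed in limma, 522 had an unadjusted p below 0.05 (114 higher and 408 lower), edgeR called 0 and DESeq2 called 9, and limma called 1 without 5A-NG4 IP5A replicate 1. RpS5a differed by log2 0.30 (limma adjusted p = 0.985) and RpS5b by -0.33 (limma adjusted p = 0.948). The lists of cytoplasmic ribosomal proteins, mitochondrial ribosomal proteins, oxidative phosphorylation, glycolysis and proteasome passed camera with medians of -0.27, -0.28, -0.30, -0.21 and -0.14 (camera adjusted p = 6.36e-15, 1.55e-12, 1.88e-07, 0.00285 and 0.00628, and adjusted p = 0.734 to 0.851 with an estimated correlation). None of their member genes passed over all genes, 2 glycolysis genes passed lower and no member of the other 4 did adjusted over the list alone, and fry passed none of the 5 lists. The proteasome call ended without 5A-NG4 IP5A replicate 1 (-0.09) or 5A-NG4 input replicate 1 (-0.12), with sample weights (-0.08) and without the 6 libraries (-0.05). With the replicate block the TCA cycle (median -0.11) and mitochondrially encoded (0.39) lists passed (camera adjusted p = 0.0356 and 0.0499, and adjusted p = 0.669 and 0.733 with the block and an estimated correlation). The mitochondrially encoded list also passed without 5A-NG4 input replicate 1 (1.25) or 5A-NG4 IP5A replicate 2 (0.91) or 3 (1.06). TCA cycle passed without 5A-NG4 input replicate 2 or 3, 5A-NG4 IP5A replicate 2, WT input replicate 2 or WT IP5A replicate 3 (-0.13 to -0.11). Yolk and secretory genes passed higher without 5A-NG4 input replicate 1 (0.36 and 0.15), and muscle without 5A-NG4 IP5A replicate 1 (0.35) or WT IP5A replicate 1 (0.13). All 3 also passed with sample weights and without the 6 libraries, where germline genes passed lower (-0.13 and -0.13). For 7 uncalled lists (yolk, chorion, follicle cell, small nuclear and nucleolar RNA, translation, secretory and antimicrobial peptides) the median and the direction of the test differed in sign.

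For RpS5b the same comparison called 2 genes, both lower in 5A-NG4 and both within the rule for named genes. MED14 (FBgn0035145), a Mediator subunit, was at 4353 ± 33.8 in WT and 2319.6 ± 206 in 5A-NG4 RpS5b precipitates, with inputs at 2507 ± 166 and 2275 ± 162 (log2 -0.77 ± 0.12 SE, limma adjusted p = 0.0117). Pax (FBgn0041789), which encodes the adhesion protein paxillin, was at 1069.8 ± 35.4 and 699.9 ± 63.4, with inputs at 887 ± 108 and 966 ± 32.5 (log2 -0.75 ± 0.13 SE, limma adjusted p = 0.0375). RpS5b differed by log2 -0.08 (limma adjusted p = 1). At an unadjusted p below 0.05 there were 356 genes (200 of them higher), edgeR called 2 and DESeq2 19, and with the replicate block limma called 7. The count was 24 without 5A-NG4 IP5B replicate 1, 1 without 5A-NG4 input replicate 3 or WT IP5B replicate 3, and 0 without 5A-NG4 input replicate 1 or 2, 5A-NG4 IP5B replicate 2 or 3, WT input replicate 3 or WT IP5B replicate 1. It was also 0 in a fit of the 4 groups alone, and Pax by itself lost its call with no filter and with TMM or quantile scaling (limma adjusted p = 0.0585, 0.0948 and 0.0657).

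In that comparison 10 lists passed camera, all lower. The medians were -0.13 for cytoplasmic and -0.02 for mitochondrial ribosomal proteins, -0.07 for proteasome, -0.24 for small nuclear and nucleolar RNAs, -0.30 for yolk and vitelline membrane, -0.16 for follicle cell regulators, -0.36 for muscle, -0.64 for fat body, hemocyte and gut, -0.20 for stress and cell death and -1.09 for antimicrobial peptides. Camera adjusted p ran from 4.7e-06 to 0.0366 and was an adjusted p = 0.673 to 0.918 with an estimated correlation, no member gene passed over all genes, 1 follicle cell gene passed adjusted over the list alone, and fry passed none of the 10. Without WT IP5B replicate 3 they ended, by list, for cytoplasmic ribosomal 0.01, mitochondrial ribosomal 0.05, proteasome -0.01, yolk -0.11, follicle cell 0.05, muscle -0.02, small RNA -0.02 and stress -0.12, and without 5A-NG4 IP5B replicate 1 for cytoplasmic ribosomal 0.03 and proteasome 0.06, while mitochondrial ribosomal proteins then passed in the other direction (0.16, camera adjusted p = 0.000183). They ended without 5A-NG4 IP5B replicate 2 for yolk -0.09, follicle cell -0.10, muscle -0.25 and fat body -0.30, without 5A-NG4 IP5B replicate 3 for yolk -0.10, follicle cell -0.04, muscle -0.18, fat body -0.64 and small RNA -0.08, without WT IP5B replicate 1 for mitochondrial ribosomal -0.03 and proteasome -0.03, and without WT IP5B replicate 2 for fat body -0.55. Among inputs, leaving out 5A-NG4 replicate 1 ended proteasome -0.05, follicle cell -0.13, fat body -0.25 and small RNA -0.19 and turned yolk 0.08, 5A-NG4 replicates 2 and 3 ended mitochondrial ribosomal -0.02 and -0.02, WT replicate 1 proteasome -0.06, WT replicate 2 mitochondrial ribosomal -0.01, proteasome -0.05 and small RNA -0.14, and WT replicate 3 follicle cell -0.15 and fat body -0.49. With the replicate block the follicle cell call ended (camera adjusted p = 0.057) and the chorion list passed (median -0.25, camera adjusted p = 0.0277, and adjusted p = 0.713 with the block and an estimated correlation). No filter ended antimicrobial peptides -0.53, proteasome -0.07, follicle cell -0.16, fat body -0.24 and small RNA -0.11, quantile scaling ended mitochondrial ribosomal -0.02, follicle cell -0.14, fat body -0.47 and small RNA -0.16, and sample weights ended cytoplasmic ribosomal 0.02, mitochondrial ribosomal 0.07, proteasome 0.01, follicle cell -0.14 and small RNA 0.13. Without the 6 libraries proteasome 0.14, yolk -0.09, follicle cell -0.09 and fat body -0.20 ended, and cytoplasmic ribosomal 0.12 and mitochondrial ribosomal 0.18 passed higher. Oxidative phosphorylation, uncalled here (median -0.07), passed higher without 5A-NG4 IP5B replicate 1 (0.18) or the 6 libraries (0.20), and lower without 5A-NG4 IP5B replicate 2 (-0.20) or 3 (-0.21) or WT IP5B replicate 2 (-0.15). For TCA cycle, long non-coding RNA and translation factor lists, none of them called, the median and the direction of the test differed in sign.

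The ratios of precipitate over input were compared across the 9031 genes, which are not independent replicates. Between WT and 5A-NG4 they had a Pearson r of 0.885 and a Spearman rho of 0.865 for RpS5a, and 0.876 and 0.883 for RpS5b. For RpS5a between WT and RpS5b-null ovaries r was 0.560 and rho 0.422, and 65.4% of genes had the same sign. None of these pairs shares a library. Of the genes higher with RpS5a in WT, 1796 were also higher in 5A-NG4 (553 by chance) and 707 in RpS5b-null ovaries (285 by chance), and of those lower 2104 (641) and 715 (262). For RpS5b, 1788 were higher (518 by chance) and 1797 lower (594 by chance) in both WT and 5A-NG4. The RpS5a and RpS5b ratios of WT ovaries share their inputs, which alone raises a correlation. Their r was -0.0657, rho -0.390 and covariance -0.0333. In 20 simulations with shared inputs and no change, mean covariance was 0.0449. Simulated r (mean 0.499) lacks real change, so is no baseline. Genes higher with both paralogs numbered 254 (506 if independent) and genes lower with both 252 (576 if independent), while 719 of those higher and 1184 of those lower with RpS5a went the other way with RpS5b.

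The authors' own tables hold the 5 precipitate over input comparisons, with an adjusted p for 9318 genes in each. At an adjusted p below 0.05 they list 4733 genes for WT IP5A (2410 higher and 2323 lower), 4466 for WT IP5B (2207 and 2259), 2643 for 5Bko IP5A (1438 and 1205), 5040 for 5A-NG4 IP5A (2416 and 2624) and 4686 for 5A-NG4 IP5B (2373 and 2313). Of these genes, 4429, 4204, 2198, 4764 and 4410 were also called in limma here, and 100% of those tested in both had the same sign. Both sets of calls come from the same libraries and are no independent evidence for each other.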

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

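Of the tests in this part, those on scaling, on carry-over of input, on germ-cell share, on libraries that stand apart and on pairs of libraries were chosen only after the result was seen. The first pattern and the list values further on stand out because mutant and WT ovaries differ in a test of the difference between their ratios, and the other 2 patterns were picked to weigh after their values were seen.

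The first pattern is that ribosomal protein mRNAs were less depleted from RpS5a precipitates in RpS5b-null than WT ovaries, among 2209 genes that differed. Medians were 0.81 for cytoplasmic and 0.68 for mitochondrial ribosomal proteins, 0.80 for oxidative phosphorylation and 0.83 for proteasome. The tables argue against carry-over of input, since small nuclear and nucleolar RNAs were at a median of 21.8% of input (upper quartile 42.1%) where 60.4% would be needed (lower quartile 48.6%). They also argue against the authors' scaling (lowest median 0.88, lower quartile 0.64). Of 100 drawn splits within genotypes, 8 gave as many genes as the real 2209 (highest other 3548), so chance is not excluded. The 7 others kept a real division of precipitates from inputs. Of 10 splits of whole pairs, too few for a share under 0.05, all but the real gave 0. Gene length, an echo of changed inputs or cell types, and smaller ratios in general (SD 0.494 against 0.669) stay untested for these mRNAs. So does a change in which ribosomes carry RpS5a, a hypothesis.

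The second pattern is the higher level of ribosomal protein, proteasome and respiratory chain mRNAs with RpS5b than with RpS5a in WT ovaries. The tables argue against the authors' scaling (lowest median of ribosomal proteins 1.17, lower quartile 0.98) and against the WT replicate 3 libraries that stand apart (1.15 without them, lower quartile 0.96). Germline genes as a set did not rise alike, at a median of -0.20 (upper quartile 0.12) where ribosomal proteins had a lower quartile of 1.05. That median lay near the -0.24 of all genes, while follicle cell regulators, muscle genes and yolk and vitelline membrane genes fell. Values are relative, so more germ-cell RNA could show as a fall of somatic lists alone. A larger share of germ-cell RNA in the RpS5b precipitates therefore stays open. Gene length and non-specific binding stay open, since there is neither a length table nor a mock precipitate, and a preference of each paralog for certain mRNAs stays a hypothesis.

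The third pattern is the higher level of follicle cell regulator and muscle mRNAs in RpS5b-null inputs. A lower share of germ cells that raised every other cell type alike is argued against by the chorion genes of late follicle cells, at a median of -2.02 (upper quartile -1.51) where muscle genes had a lower quartile of 2.00. Scaling was first tested on both lists together, which left it open, and the lists were parted once that was seen, with the bound of 0.5 for a lower quartile also written after the result. By list, scaling is argued against as the whole cause for muscle (lowest median 1.91, lower quartile 1.70). Follicle cell regulators kept their call with both scalings, at medians of 2.18 (TMM, lower quartile 1.35) and 2.29 (quantile), though TMM moved the median of all genes from 0.13 to -0.17, which counts against scaling as the whole cause. With quantile scaling their lower quartile was 0.36, under that bound, so a part of the rise in the lowest members stays open to it. Ovaries with fewer late egg chambers, or with other tissue attached, stay open and untested.

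The other differences are values alone. Of 1552 genes with unchanged input 32.8% differed in the RpS5a ratios of RpS5b-null against WT ovaries, and of 6797 with changed input 23.7%, so those differences are not confined to genes with changed input, but all 83 tested cytoplasmic ribosomal protein genes had changed input and are not among the 1552. In RpS5a ratios between RpS5b-null and WT ovaries, list medians were 0.52 for glycolysis, 0.24 for translation factors, -0.63 for yolk and vitelline membrane, -1.22 for chorion, -0.63 for follicle cell regulators and -0.62 for muscle. Without 5Bko IP5A replicate 1 the chorion median was -0.17 and the yolk median -0.31, and the translation factor call ended without 5Bko IP5A replicate 3 (0.23) or 5Bko input replicate 1 (0.21). In RpS5a ratios between 5A-NG4 and WT ovaries, medians were -0.27 for cytoplasmic and -0.28 for mitochondrial ribosomal proteins, -0.30 for oxidative phosphorylation, -0.21 for glycolysis and -0.14 for proteasome, and the last call ended without 5A-NG4 IP5A replicate 1 (-0.09) or 5A-NG4 input replicate 1 (-0.12). In RpS5b ratios between 5A-NG4 and WT ovaries 2 genes differed, and medians were -0.13 for cytoplasmic and -0.0181 for mitochondrial ribosomal proteins, -0.30 for yolk and vitelline membrane, -0.16 for follicle cell regulators, -0.36 for muscle, -0.64 for fat body, hemocyte and gut, -0.24 for small nuclear and nucleolar RNAs, -0.0665 for proteasome, -0.20 for stress and cell death and -1.09 for antimicrobial peptides. The libraries that end these last calls stand with the comparison in the report.

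Other splits of the same libraries were counted for each comparison. The 8 comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05, and in each 1 split, the real one, gave as many genes. Real counts and the highest of the other splits were 4461 and 0 (WT IP5A), 4377 and 0 (WT IP5B), 6643 and 0 (RpS5b against RpS5a), 2217 and 0 (5Bko IP5A), 4828 and 1 (5A-NG4 IP5A), 4585 and 1081 (5A-NG4 IP5B), 6797 and 0 (5Bko input) and 791 and 0 (5A-NG4 input). The split with 1081 genes parted fewer than 3 of the pairs, and among the 4 splits that parted 3 pairs the highest other count was 0. For RpS5b ratios of 5A-NG4 13 of 100 drawn splits gave at least the real 2 genes (highest 4776), so chance is not excluded. For RpS5a ratios of 5A-NG4 the real count in limma was 0 (522 at an unadjusted p below 0.05, 0 in edgeR and 9 in DESeq2), which any of the 100 splits must reach (highest 5706), so they say nothing of chance. Splits with several times the real count point to a structure of the samples, since 11 of the 12 others with as many RpS5b genes kept a real division of precipitates from inputs. Splits of whole pairs, 10 for each and too few for a share under 0.05, gave real counts of 0 and 2 and highest others of 0 and 1.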

How the results depend on the processing

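The fits without the 6 libraries, fry, and camera with both an estimated correlation and the block were chosen after results were seen. Counts of changed genes for the 8 comparisons of 2 groups and for RpS5a in RpS5b-null against WT stayed within 1.5 times of the value in the report with pseudocounts of 0.5 and 10, both filters, TMM, quantile scaling, edgeR, DESeq2 and the block. The exceptions under other settings follow, and the cause was not tested. Precipitate over input ratios are abbreviated as RpS5a or RpS5b ratios.

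In a fit of the groups compared alone, 5A-NG4 IP5B over input had 3038 genes, and the RpS5a and RpS5b ratios of 5A-NG4 against WT had 3 and 0. Those 2 counts were 1 and 1 with no filter, 1 and 1 with TMM scaling, and 9 and 19 with DESeq2. With sample weights the counts were 7267 (WT IP5B), 4040 (5Bko IP5A), 7128 (5A-NG4 IP5B), 4031 (5A-NG4 input), 5001 (RpS5a ratios of RpS5b-null against WT), 1663 (RpS5a ratios of 5A-NG4) and 2967 (RpS5b ratios of 5A-NG4). The fit of those weights reported slow convergence, so these counts, and calls that end or pass with them, are uncertain. Without the 6 libraries they were 3861 (5Bko IP5A), 2179 (5A-NG4 input), 3676 (RpS5a ratios of RpS5b-null), 108 (RpS5a ratios of 5A-NG4) and 78 (RpS5b ratios of 5A-NG4).

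With the replicate block the RpS5b ratios of 5A-NG4 against WT had 7 genes and the RpS5a ratios 0. The other blocked counts were 5105 (WT IP5A), 5247 (WT IP5B), 3096 (5Bko IP5A), 5421 (5A-NG4 IP5A), 5402 (5A-NG4 IP5B) and 3120 (RpS5a ratios of RpS5b-null). Where numbers do not pair, the block gave 7121 (RpS5b against RpS5a), 6994 (5Bko input) and 941 (5A-NG4 input). There the fat body, hemocyte and gut list passed for RpS5b against RpS5a (camera adjusted p = 0.0298, and 0.669 with an estimated correlation). In no comparison of 2 groups did every library correlate best with its own number. Of named genes and lists, beyond those given, the block changed only wupA in 5Bko IP5A, whose call ended (limma adjusted p = 0.0770).

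Leaving out 1 library at a time, the 5A-NG4 input count ran from 498 (without WT input replicate 1) to 790. The RpS5a ratios of 5A-NG4 against WT had 0 to 1 genes, with 1 without 5A-NG4 IP5A replicate 1. The RpS5b ratios had 0 to 24, with 24 without 5A-NG4 IP5B replicate 1 and those with 0 or 1 in the report. In those ratios the cytoplasmic ribosomal protein median ran from -0.25 to 0.0306, the mitochondrial one from -0.16 to 0.16, the proteasome one from -0.17 to 0.0615 (each highest without 5A-NG4 IP5B replicate 1), and the yolk and vitelline membrane one from -0.63 to 0.0770 (highest without 5A-NG4 input replicate 1). Without the 6 libraries the first 3 turned to 0.12, 0.18 and 0.14, and with sample weights the mitochondrial one to 0.0698. Ef1alpha48D, a translation elongation factor, turned to 0.29 in WT IP5A and 0.14 in 5A-NG4 IP5A with quantile scaling.

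More genes were higher than lower with quantile scaling in WT IP5A (2309 and 2068), 5A-NG4 IP5A (2628 and 2168) and 5A-NG4 IP5B (2072 and 1905), and fewer in 5Bko input (3018 and 3405). In RpS5a ratios of RpS5b-null against WT, small nuclear and nucleolar RNAs passed without 5Bko IP5A replicate 2 (0.51), WT input replicate 2 (0.53) or WT IP5A replicate 2 (0.53). In 5A-NG4 IP5A, muscle passed without IP5A replicate 1 (0.77) and yolk without input replicate 1 (0.54), and secretory genes passed in 5A-NG4 IP5B without input replicate 1 (0.25) or IP5B replicate 2 (0.18) or 3 (0.18), and in RpS5b ratios of 5A-NG4 without 5A-NG4 input replicate 1 (0.18). Long non-coding RNAs passed in WT IP5B without IP5B replicate 3 (-0.41), and small nuclear and nucleolar RNAs in 5A-NG4 input without 5A-NG4 input replicate 2 (0.35).

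Of 209 list tests, 105 passed with the preset correlation, 0 with an estimated one, 0 with an estimated one and the block, and 89 with fry, 77 of them shared. The correlation of RpS5a ratios between WT and RpS5b-null ovaries was 0.437 with no filter. For RpS5b ratios between WT and 5A-NG4 it was 0.926 with a pseudocount of 10, 0.799 with no filter, 0.937 with a filter at 100 and 0.820 with quantile scaling, and 0.830 (without 5A-NG4 input replicate 1) to 0.875 over libraries left out. At a threshold of 0.01 the authors' tables list 3889, 3313, 1881, 4232 and 3537 genes. No fit at another depth was made, and at the present depth and 3 libraries per group the simulated RpS5a ratios of RpS5b-null against WT recovered 31.3% of 67 genes changed 1.5-fold.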

Other observations

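Copies of ribosomal protein genes other than RpS5 were looked at in the RpS5b-null inputs, and those named were chosen after their values were seen. RpS19b, a germline-enriched copy of RpS19a, was at 75.2 ± 16.2 in RpS5b-null and 9.49 ± 2.64 in WT input (n = 3, log2 2.87), where RpS19a differed by log2 0.97 and the cytoplasmic ribosomal protein list had a median of 0.74. In 5A-NG4 input RpS19b was at 10.6 ± 1.25. Such copies share sequence, so their reads are uncertain.

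The libraries of a genotype share a strain background, which the design does not part from the effect of RpS5. The eye pigment transporter gene w was at 18.5 ± 2.30 in RpS5b-null, 1016 ± 60.2 in WT and 1865 ± 161 in 5A-NG4 inputs, and nrv3 at 47.9 ± 2.49, 1165 ± 138 and 7.09 ± 2.37. Xrp1 was at 420 in WT input, 855 ± 111 with RpS5a and 280.0 ± 56.7 with RpS5b.

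One hypothesis was written before its test, and a control by averaging after the result was seen. Without RpS5b, RpS5a may sit on ribosomes that both share out in WT. RpS5a ratios of RpS5b-null ovaries would follow the mean of the 2 WT ratios more than the WT RpS5a ratios. Across 9031 genes, which are not independent replicates, r was 0.618 with that mean, 0.560 with WT RpS5a and 0.302 with WT RpS5b. Averaging the RpS5a ratios of WT and 5A-NG4 instead gave 0.543, and in a joint fit the slopes were 0.43 on RpS5a and 0.22 on RpS5b. With 1 of 15 libraries left out the first 2 r ran from 0.559 to 0.658 and 0.496 to 0.587, overlapping. The prediction held, but small nuclear and nucleolar RNAs fell in each ratio, which can raise r, so it does not decide. Changed cell types stay open too.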
